A study of Homo sapiens with 17 samples.

How the data were processed

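Single-cell RNA sequencing with the 10x Genomics 3' v3.1 chemistry was run on peripheral blood mononuclear cells of 9 SjD and 8 control donors in 3 cohorts. Per the labels, frozen cells were thawed, marked with hashing antibodies so that donors could be pooled, sorted for live cells that bound neither Annexin V nor a dead cell dye, and sequenced on a NovaSeq. Per the labels, the authors aligned the reads to hg38 and counted UMIs with Cell Ranger 7.0.0. For each sample a matrix of counts, that is UMI counts per gene and cell, was deposited, together with the other files of each set, the lists of barcodes and features. The matrices hold 36601 genes. Whole numbers were found throughout, with at least 1001 UMIs and 428 genes in every barcode and at most 14.99% mitochondrial UMIs, so the deposited cells had been filtered by limits that the labels do not state. The highest number of genes in a cell was nearly equal in all samples that share a barcode suffix, 2497 to 2499 for suffix 1 and 4136 for suffix 5 for example, and it differed between suffixes. Samples with the same suffix shared 0 barcodes over 22 pairs, where 212.9 would be expected by chance, and samples with different suffixes shared 1248 over 114 pairs. The suffix was therefore read as the capture pool: 1 pool for cohort 1, and for each of cohorts 2 and 3 a pool of controls and a pool of SjD samples. In cohorts 2 and 3 pool and disease cannot be told apart.

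Limits of at least 500 UMIs, 300 genes and at most 15% mitochondrial UMIs removed 0 of the 105775 barcodes. Doublets were scored per sample with the simulation method of scrublet in scanpy 1.11.5. The automatic limit called 1.28% of cells, and under 0.5% in 12 of 17 samples, so that 1 limit, a score of 0.2, was used for all samples. It left out 5648 cells (5.34%, 3.18% to 7.05% per sample). The 100127 cells left were log-normalised, variable genes were chosen within cohorts (2000 for all cells, 1500 for T and NK cells, 1000 for B cells). Genes of the interferon, IFN-γ, immediate early, ribosomal, mitochondrial, sex-linked and antigen receptor variable groups were left out of the clustering. 30 principal components were harmonised over libraries with an iterative soft-clustering correction, and cells were joined to 20 neighbours and clustered with leidenalg 0.10.2 at a resolution of 1.2 for all cells, 2 for T and NK cells and 1 for B cells. The group was not used in any of these steps. Clusters were named by the fixed marker list with the highest mean standardised expression, when at least 3 of its markers were found in 5% or more of the cells and it led the next lineage by 0.1. A cluster in which markers of more than 1 lineage reached 0.3 of their highest cluster mean, or whose 10 leading genes held more fixed markers of another class than of its own, was left without a name. This comparison used the markers of the same clustering level, so it let 2 clusters with leading genes of other cell types stay among CD4 T-like cells, 1 of 324 cells led by B cell genes and 1 of 868 cells led by NK cell genes. They were kept in the main results and left out in an alternative. Class names carry "-like" since they rest on RNA alone. Antigen-experienced T cells were clustered again at a resolution of 2, and memory CD4 T-like clusters whose Th1 markers lay over 0.5 SD above the mean of such clusters, with at least 3 markers detected, were called Th1-like.

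The SjD coefficient of log2 shares, with 0.5 added to the cells and 1 to the total, was tested with cohort in the model by an exact two-sided permutation test of the labels within cohorts (4000 arrangements, smallest possible p 0.00025), with Benjamini-Hochberg adjustment over the 30 shares. Cells with a UMI of IFNG or FOXP3 were counted after thinning each cell to 1500 UMIs, with shallower cells left out, and to 1000 as an alternative. For the comparison of genes, UMIs were summed per sample and class, classes with under 10 cells in a sample were to be left out for that sample (none was). Y-linked genes, XIST and TSIX were removed. The counts were fitted with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test with cohort in the model) in R 4.3.3, with an adjusted p under 0.05 within each of the 7 classes. Means and SD are of counts per 1000000 (CPM) over samples, and errors of log2 changes are SE. 27 gene lists were fixed, of which 26 had enough members in a class. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 165 tests, and with an estimated correlation and fry beside it. Type I interferon scores, the mean log2 CPM of the list, were tested by exact permutation. DESeq2 1.42.0 served as the other tool. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Coordinates are from GENCODE 29 on GRCh38.

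Genes were named by a rule: in CD4 T-like and CD14 monocyte-like cells the 12 higher and 12 lower genes with the smallest p among those passed, in the other classes 5 and 5, then a set of fixed genes where tested, and from each called list the 4 members with the smallest p. The text names a part of the last group, and a few genes that fall under the rule are not reported here. Genes with common deletions in people, antigen receptor variable genes, polymorphic HLA class II genes other than HLA-DRA and clone-named transcripts were not named. The groups, tests, gene lists, naming rule, depth limits and most alternatives were set before the data were examined. The harmonisation over libraries, the single doublet limit, the naming thresholds of clusters and the Th1 scoring rule were set after they were seen, as were the alternatives within cohorts, within naive, memory or other parts of a class, with a doublet score limit of 0.1, with other clustering seeds and with the clusters led by B or NK markers left out.

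The total UMIs per sample and class ranged from 61351 in Treg-like cells to 18325700 in CD4 T-like cells, and the fewest cells of a sample were 28 (CD16 monocyte-like), 30 (Treg-like) and 103 or more in the other classes. Tested on simulated data with 200 changed genes per class, the fit recovered 31.3% to 56.7% of changes of 1.5-fold, 73.1% to 88.1% of changes of 2-fold and 84.8% to 97.0% of changes of 4-fold, with 2.13% to 7.09% false calls. The simulated counts were drawn for each gene on its own, without pool effects. The rates therefore do not cover genes that vary together or differences between pools. The sample numbers are donor numbers within each group, so they pair no samples: 1 of 8 SjD samples correlated best with the control of the same number in CD4 T-like cells and 1 of 8 in CD14 monocyte-like cells. No 2 samples of a group held the same library (64 pairs, lowest chi-square per degree of freedom 3.04). Alternatives were RLE size factors, DESeq2, no count filter, no cohort term, a block by sample number, doublets kept, finer clustering, 2 other clustering seeds, a mitochondrial limit of 10%, at least 30 cells per sample and leaving out each sample. A rerun of the same scripts under other processor settings gave other clusters, since rounding differences grow in the harmonisation and clustering. The processor settings were then fixed in the scripts, the values given here are those of the fixed settings, and the 2 other seeds were added to show how far the values move with the clustering.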

Results

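Peripheral blood mononuclear cells (PBMC) from 9 patients with Sjögren's disease (SjD), a systemic autoimmune disease that affects the salivary and tear glands, and from 8 control donors were profiled by droplet-based 3' single-cell RNA sequencing. The sample labels call the control donors healthy, and the series description calls them non-SjD controls. The samples came in 3 cohorts: cohort 1 held 3 SjD and 2 control samples, and cohorts 2 and 3 held 3 SjD and 3 control samples each. The matrices held 105775 cells, 58504 from SjD and 47271 from control samples, with 2404 to 9665 cells per sample. The total count per sample ran from 5800283 to 42315613 UMIs, from 10167211 upward in SjD and from 5800283 to 39361601 in control samples. The median depth per cell was 2141.5 to 2478 UMIs in the samples of cohort 1, 2940.5 to 3574.5 in cohort 2 and 4465 to 5269 in cohort 3. The barcode suffixes put all samples of cohort 1 into 1 capture pool, while in cohorts 2 and 3 the SjD samples and the control samples each had a pool of their own. Values for cohort 1 alone, the only cohort in which both groups shared a pool, therefore stand beside the main results. With 3 samples against 2, an exact test within cohort 1 has 10 arrangements and cannot go below p = 0.1.

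Which cell types of the blood differ in abundance between patients and controls was the first comparison. B-like cells made up 22.4% ± 12.2 (SD, n = 9) of the cells of SjD samples and 10.3% ± 2.76 (SD, n = 8) of those of control samples. Naive B-like cells made up 14.98% ± 9.58 (SD, n = 9) against 6.25% ± 2.53 (SD, n = 8). CD4 T-like cells took the smaller share in SjD, 32.8% ± 11.5 (SD, n = 9) against 49.4% ± 8.46 (SD, n = 8). Mucosal-associated invariant T (MAIT)-like cells, a T cell type that recognises microbial vitamin B metabolites, took a smaller share too, with 0.331% ± 0.50 (SD, n = 9) against 0.874% ± 0.678 (SD, n = 8). Among CD8 T-like cells, naive-like cells were 18.2% ± 15.8 (SD, n = 9) in SjD and 36.6% ± 18.8 (SD, n = 8) in control samples. Cytotoxic-like cells, which express granzymes and perforin, were 61.8% ± 16.1 (SD, n = 9) and 47.8% ± 19.8 (SD, n = 8).

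None of the 30 shares compared passed the adjusted threshold in the two-sided exact permutation test within cohorts, while 9 had an unadjusted p under 0.05. By edgeR on the cell counts, 2 shares passed. The B-like share differed by 1.03 on the log2 scale (exact permutation p = 0.0035, adjusted p = 0.0563), with 8 of 9 SjD samples above the control mean of their cohort. By edgeR the adjusted p was 0.0334. The naive B-like share differed by 1.17 (exact permutation p = 0.00375, adjusted p = 0.0563), also with 8 of 9 SjD samples higher, and its adjusted p by edgeR was 0.0334. The CD4 T-like share differed by -0.65 (exact permutation p = 0.01, adjusted p = 0.0996), with 2 of 9 SjD samples above their cohort's control mean. The MAIT-like share differed by -1.75 (exact permutation p = 0.021, adjusted p = 0.0996), with 1 of 9 above it. It rests on few cells in some samples, with 1 in SjD 9, 5 in SjD 4 and 5 to 8 in each sample of cohort 1. Within cohort 1 the MAIT-like log2 difference was -0.78 (exact permutation p = 0.2). The naive-like share of CD8 T-like cells differed by -1.30 (exact permutation p = 0.0143, adjusted p = 0.0996, 1 of 9 SjD samples above). The cytotoxic-like share differed by 0.40 (exact permutation p = 0.179, adjusted p = 0.298, 7 of 9 above). Within the single pool of cohort 1, B-like cells were 10.8% in SjD and 8.78% in control samples, a log2 difference of 0.31 (exact permutation p = 0.5), and the log2 difference of the CD4 T-like share was -0.27. Naive B-like cells were 7.05% and 5.79% there, a log2 difference of 0.27 (exact permutation p = 0.6). Clusters left without a name held 9.64% ± 4.91 (SD, n = 9) of SjD and 7.35% ± 4.53 (SD, n = 8) of control cells, and 15.2% and 14.1% in cohort 1.

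**Figure D1:**
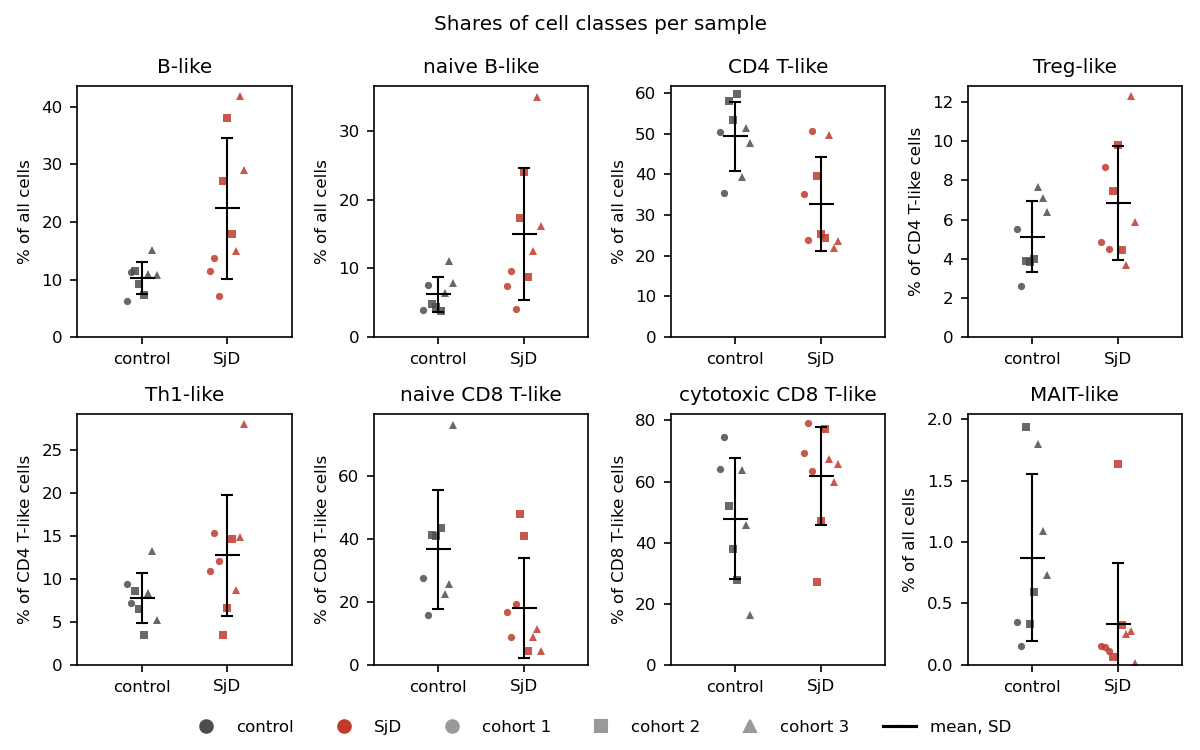
Share of cells of each class per sample, in percent or of the parent class named on the axis, marker shape gives the cohort, points are samples, bars are group means with SD. B-like cells averaged 22.4% in SjD and 10.3% in control samples, and CD4 T-like cells 32.8% and 49.4%.

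Regulatory T (Treg) cells, which restrain immune responses under the transcription factor FOXP3, and interferon-gamma (IFN-γ)-producing Th1 cells are the T cell types named in the series title. Treg-like cells made up 6.85% ± 2.93 (SD, n = 9) of the CD4 T-like cells of SjD samples and 5.12% ± 1.80 (SD, n = 8) of those of control samples. Of all cells, they were 2.06% ± 0.619 (SD, n = 9) and 2.51% ± 0.822 (SD, n = 8). Th1-like cells made up 12.7% ± 6.98 (SD, n = 9) of CD4 T-like cells in SjD and 7.75% ± 2.91 (SD, n = 8) in control samples.

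Neither share of CD4 T-like cells passed the exact permutation test, which does not show that the groups are equal. The Treg-like share of CD4 T-like cells differed by 0.42 on the log2 scale (exact permutation p = 0.166, adjusted p = 0.292 among the 30 shares, 7 of 9 SjD samples above their cohort's control mean). As a share of all cells the Treg-like class differed by -0.23 (exact permutation p = 0.4). The Th1-like share of CD4 T-like cells differed by 0.58 (exact permutation p = 0.097, adjusted p = 0.198, 8 of 9 above), with doublets kept by 0.99 (exact permutation p = 0.0107) and under 2 other clustering seeds by 0.30 and 0.42 (exact permutation p = 0.411 and 0.295). The Treg-like share differed by 0.40 and 0.25 under these seeds. Within cohort 1 the log2 differences were 0.59 for Treg-like (exact permutation p = 0.6) and 0.62 for Th1-like cells (exact permutation p = 0.1). They were 0.82 and 0.26 in cohort 2 and -0.12 and 0.88 in cohort 3, so the Treg-like difference did not keep its direction over the cohorts.

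IFNG, which encodes IFN-γ (GRCh38, chromosome 12, 68154768 to 68159747), was detected mainly in CD8 T-like and NK-like cells. After thinning each cell to 1500 UMIs, 5.23% ± 2.37 (SD, n = 9) of CD8 T-like cells of SjD samples held an IFNG UMI, against 3.503% ± 2.48 (SD, n = 8) in control samples. In NK-like cells the shares were 4.83% ± 2.16 (SD, n = 9) and 8.82% ± 8.22 (SD, n = 8), and in CD4 T-like cells 1.15% ± 0.761 (SD, n = 9) and 0.993% ± 1.00 (SD, n = 8). Monocyte-like cells, which are not a known source of IFN-γ, gave a background of 0.326% in SjD and 0.401% in control samples. FOXP3 (chromosome X, 49250436 to 49264826) was found in more CD4 T-like cells of SjD samples, 0.573% ± 0.328 (SD, n = 9), than of control samples, 0.336% ± 0.130 (SD, n = 8), with 0.0346% and 0.0696% in monocyte-like cells.

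The FOXP3 share, tested on its own, rose by 0.63 on the log2 scale (exact permutation p = 0.0385, 9 of 9 SjD samples above their cohort's control mean). With cells thinned to 1000 UMIs the exact permutation p was 0.0795 and without thinning 0.0875, and leaving out single samples ended the call in 6 of 17 cases. Within cohort 1 the log2 difference was 0.78 (exact permutation p = 0.4). None of the IFNG shares passed the exact permutation test over all samples. The exact permutation p for IFNG was 0.165 in CD8 T-like cells (adjusted p = 0.299, log2 difference 0.65, 6 of 9 SjD samples above their cohort's control mean). It was 0.2 in NK-like cells (adjusted p = 0.299, log2 difference -0.55, 1 of 9 above) and 0.461 in CD4 T-like cells (adjusted p = 0.461, log2 difference 0.39, 6 of 9 above). The median depths before thinning were 2745.5 UMIs in SjD and 3555 in control samples for CD4 T-like cells, 3360 and 3709.5 for CD8 T-like cells, 3130 and 2899.25 for NK-like cells and 5470 and 5431.5 for monocyte-like cells. Cells too shallow to be thinned numbered 2638 and 1965 among CD4 T-like cells, 1085 and 321 among CD8 T-like cells, 569 and 375 among NK-like cells and 125 and 80 among monocyte-like cells. Without thinning, IFNG was found in 10.1% and 7.07% of CD8 T-like, 8.38% and 12.7% of NK-like and 2.22% and 1.86% of CD4 T-like cells, and FOXP3 in 1.14% and 0.778% of CD4 T-like cells. Leaving out control 8 brought the NK-like IFNG difference to -0.82 with exact permutation p = 0.01.

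Genes induced by type I interferon, the antiviral cytokine family, were higher in SjD in all 7 cell classes tested. The mean expression of the fixed list of such genes was 4.63-fold higher in CD14 monocyte-like cells, 3.63-fold in B-like cells, 3.32-fold in CD16 monocyte-like cells, and 2.66-fold to 2.90-fold in NK-like, Treg-like, CD4 T-like and CD8 T-like cells. IFI44L (chromosome 1, 78619922 to 78646145), an interferon-induced gene, rose in 7 of 7 classes by 3.31 to 4.54 on the log2 scale. ISG15 (chromosome 1, 1001138 to 1014540), a ubiquitin-like antiviral modifier, rose in all of them by 1.29 to 2.53. MX1 (chromosome 21, 41420304 to 41459214), a GTPase that blocks viruses, rose in 7 of 7 classes by 1.75 to 2.29. IFI27 (chromosome 14, 94104836 to 94116698), an interferon-induced mitochondrial protein, rose by 4.22 to 6.86 in the 6 classes in which it could be tested.

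The exact permutation p of the list's mean was 0.0005 to 0.001 over the 7 classes (adjusted p = 0.000875 to 0.001), with at least 8 of 9 SjD samples above their cohort's control mean in every class. The difference was larger than in CD4 T-like cells by 0.63 on the log2 scale in CD14 monocyte-like and by 0.32 in B-like cells (adjusted p = 0.00375 each), and by 0.31 in CD16 monocyte-like cells (adjusted p = 0.0415, exact permutation test over the 17 members tested in all classes). GBP1, a GTPase that responds most to IFN-γ, passed in 1 of 7 classes, CD14 monocyte-like cells, with log2 values of 0.60 to 1.68 over the classes. In cohort 1 alone the list's mean differed by 0.72 to 1.94 on the log2 scale over the classes (exact permutation p = 0.2 to 0.3), in the same direction as in all samples. That difference came mainly from SjD 1 and SjD 2, which lay above both controls of the cohort in every class. SjD 3 lay between these controls in CD4 T-like (4.37 against 4.27 and 4.74), Treg-like, NK-like and CD16 monocyte-like cells. It lay above both in CD8 T-like, B-like and CD14 monocyte-like cells.

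**Figure D2:**
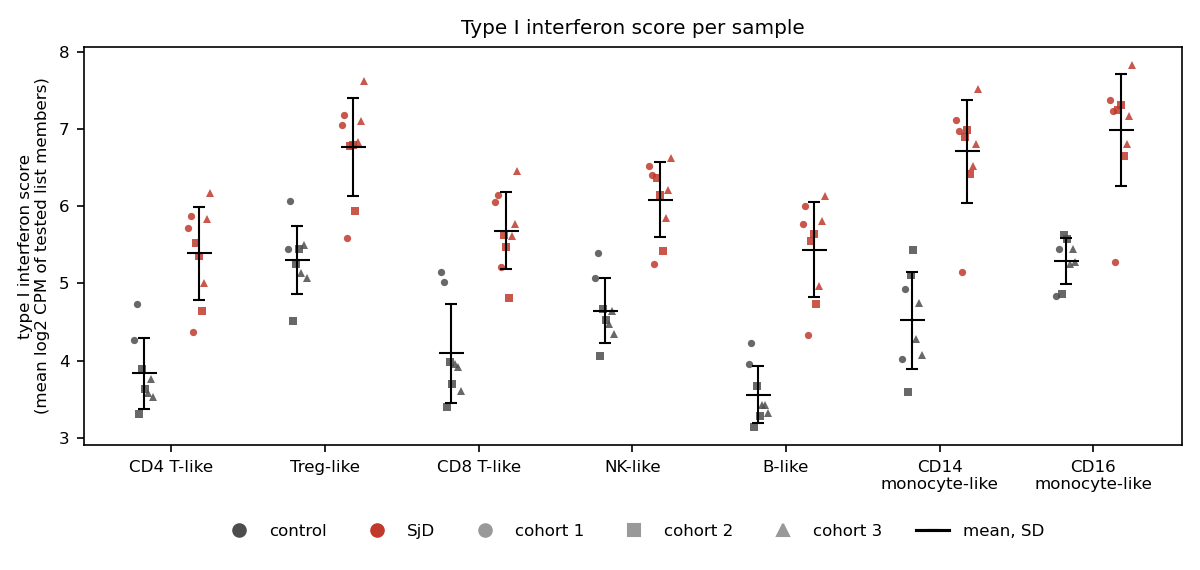
Mean log2 CPM (counts per 1000000) of the type I interferon list per sample in the 7 cell classes. Points are samples and bars are group means with SD (9 SjD, 8 control). SjD means lie above control means in all 7 classes, with the widest gap, 4.63-fold, in CD14 monocyte-like cells.

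CD4 T-like cells (40486 cells) carried a broad change: of 13418 genes tested, 159 rose and 128 fell in SjD (edgeR, adjusted p under 0.05). Together they ranged from 127 without SjD 8 to 436 without SjD 7. Interferon-induced genes rose together, among them IFI44 by 2.00 ± 0.25 on the log2 scale (SE, n = 17, adjusted p = 0.00073, 88.7 ± 36.2 counts per 1000000, CPM, in SjD and 22.8 ± 6.13 in control samples, SD). PLSCR1, a phospholipid scramblase, rose by 1.57 ± 0.21 (adjusted p = 0.000889), and IFI35, an interferon-induced protein, by 0.98 ± 0.13 (adjusted p = 0.000889). IFI44, PLSCR1 and IFI35 were higher in 9 of 9 SjD samples, and IFI44L and MX1 in 8 of 9. IL12RB2, the IL-12 receptor chain of Th1 cells (chromosome 1, 67307364 to 67397090), rose by 1.78 ± 0.36 (adjusted p = 0.0126, 53.2 ± 34.0 CPM against 15.4 ± 9.65, 8 of 9 SjD samples higher, 1.52 in cohort 1). Ribosomal protein genes fell together, such as RPS3 by 0.54, RPL3 by 0.54 and RPL39 by 0.47 on the log2 scale, each lower in 9 of 9 SjD samples.

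Of 29 measured type I interferon genes in CD4 T-like cells, 27 rose (median log2 change 1.52, 27 when adjusted over the list alone). Of 13 genes of the IFN-γ response, 4 rose (median 0.39, 6 when adjusted over the list alone), including GBP5, a GTPase, by 0.63 and TAP1, which loads peptides for MHC class I, by 0.64. With an estimated correlation the adjusted p of the 2 lists was 0.0664 and 0.185. The MHC class II list rose with 7 of 9 members (9 when adjusted over the list alone, median 0.83, adjusted p = 0.0686 with an estimated correlation), among them HLA-DRA by 0.93 and CD74, the invariant chain, by 0.60. Both genes are abundant in B cells. Markers of B cells were higher in these T-like cells: of 8 B cell markers 7 passed (8 when adjusted over the list alone, median 1.13, adjusted p = 0.0529 with an estimated correlation). Among them, IGKC, an antibody light chain, rose by 1.28, MS4A1, which encodes CD20, by 1.00, and BANK1, a B cell adaptor, by 1.09. IGHM, the IgM heavy chain, rose by 1.6 ± 0.17 (adjusted p = 0.000181, 41.8 ± 9.89 CPM against 14.5 ± 3.43), PAX5, the B lineage transcription factor, by 1.26, and JCHAIN, which joins IgM and IgA units, by 1.72. In the single pool of cohort 1 the median of the B cell markers was 0.22, with 0.60 for IGHM, 0.01 for IGKC and -0.26 for JCHAIN. NIBAN3, a gene expressed mainly in B cells, rose by 1.29 ± 0.18 (adjusted p = 0.000889). MZB1, a chaperone of antibody assembly, rose by 1.5 and TCF4, a transcription factor of plasmacytoid dendritic cells, by 1.25. Their log2 changes in cohort 1 alone were 0.51, 1.33 and 0.97, and 0.85 for PAX5. The class held 2 clusters with leading genes of other cell types, 1 of 324 cells led by B cell genes (1.08% of SjD and 0.58% of control CD4 T-like cells) and 1 of 868 cells led by NK cell genes (2.95% and 1.501%). The cells led by NK cell genes were most frequent in cohort 1, in both groups. They numbered 56 to 174 per sample there, among 1143 to 2745 CD4 T-like cells. In cohorts 2 and 3 they numbered 5 to 82, among 1223 to 4800. Their percentages over all samples therefore mix cohort with group. With both clusters left out, the median of the B cell markers was 1.03, and -0.14 in cohort 1. There TCF4 was at 0.56, and MZB1 and PAX5 had too few counts to be tested. The atypical B cell list rose as well (2 of 12 members, 8 higher and 1 lower when adjusted over the list alone, median 0.69, adjusted p = 0.11 with an estimated correlation), with SOX5, a transcription factor, at 1.219 and FCRL5, an Fc receptor-like protein, at 1.29.

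Among T cell programmes in CD4 T-like cells, the Th1 list was higher (median 0.58, camera adjusted p = 0.00819, and adjusted p = 0.587 with an estimated correlation), with 1 of 14 members past the threshold, IL12RB2, and 2 when adjusted over the list alone. In cohort 1 the list's median was -0.09. TBX21, the master transcription factor of Th1 cells, had a log2 value of 0.66 (adjusted p = 0.24), CXCR3, their chemokine receptor, 0.76 (adjusted p = 0.249) and IFNG 0.12 (adjusted p = 0.942). The Treg identity list was higher (median 0.23, camera adjusted p = 0.0361, and adjusted p = 0.489 with an estimated correlation), with 0 of 15 members past the threshold in edgeR, 6 at an unadjusted p under 0.05 and 1 over the list alone. FOXP3 had a log2 value of 0.63 (adjusted p = 0.257), IKZF2, the Treg transcription factor Helios, 0.54 (adjusted p = 0.325). IL2RA, a chain of the IL-2 receptor, had -0.15 (adjusted p = 0.679) and CTLA4, an inhibitory receptor, -0.12 (adjusted p = 0.747). The exhaustion list (median 0.45, camera adjusted p = 0.0131, and adjusted p = 0.372 with an estimated correlation) had 0 of 9 members past the threshold in edgeR (4 at an unadjusted p under 0.05) and 4 when adjusted over the list alone. TOX, a transcription factor of exhausted T cells, had a log2 value of 0.92 (adjusted p = 0.0873) and PDCD1, which encodes PD-1, 0.92 (adjusted p = 0.173). The cytotoxic list (median 0.77, camera adjusted p = 1.17e-05, and adjusted p = 0.396 with an estimated correlation) had 0 of 16 in edgeR, 10 at an unadjusted p under 0.05 and 8 over the list alone, with GZMK, a granzyme, at 1.11 (adjusted p = 0.201). With the 2 clusters led by B or NK cell genes left out, the cytotoxic list's median was 0.57 (5 of 15 members at an unadjusted p under 0.05), and -0.51 in cohort 1, against 0.19 there with them. The follicular helper list (median 0.13, camera adjusted p = 0.039, and adjusted p = 0.409 with an estimated correlation) had 1 of 8 members past the threshold and 2 over the list alone. The naive and memory T cell list was lower (median -0.21, camera adjusted p = 0.0139, and adjusted p = 0.505 with an estimated correlation), with 0 of 11 members in edgeR, also over the list alone, and 2 at an unadjusted p under 0.05. Naive-like cells were 41.2% of CD4 T-like cells in SjD and 52.9% in control samples (exact permutation p = 0.0865). Within naive-like cells alone the cytotoxic list's median was 1.13 (0.15 in cohort 1), and 0.59 without the cluster led by B cell genes. The naive and memory list's median was -0.14 in them (0.097 in cohort 1). For the other lists of this paragraph, values within parts of the class are not given here, so a change of makeup stays open.

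Of 82 ribosomal protein genes 53 fell in CD4 T-like cells (75 when adjusted over the list alone, median -0.39, adjusted p = 0.141 with an estimated correlation), and RLE size factors or DESeq2 did not turn the direction of any ribosomal gene named. Many of these genes have near-identical pseudogenes, which leaves the origin of their reads uncertain. The translation elongation factors EEF2 and EEF1B2 fell with them, by 0.41 and 0.60. So did CELA1, an elastase, by 1.70, PPP4R4, a phosphatase subunit, by 1.48, HOOK2, a microtubule-binding protein, by 0.53, C12orf57 by 0.50 and LINC00910, a non-coding RNA, by 0.99 on the log2 scale. Genes of the immediate early and stress response were lower as a list (median -0.55, camera adjusted p = 4.29e-05, and adjusted p = 0.505 with an estimated correlation), with 0 of 22 members past the threshold in edgeR, 14 at an unadjusted p under 0.05 and 7 when adjusted over the list alone. FOS, a subunit of the transcription factor AP-1, had a log2 value of -1.26 (adjusted p = 0.087) and FOSB -0.98 (adjusted p = 0.0684). Mitochondrially encoded genes, a sign of RNA quality, were lower as well (median -0.29, 0 of 13 past the threshold in edgeR, 10 at an unadjusted p under 0.05, 9 over the list alone, adjusted p = 0.363 with an estimated correlation). In cohort 1 alone 0 genes passed in edgeR (552 at an unadjusted p under 0.05, and 0 by DESeq2). Of the 160 genes called in cohorts 2 and 3 and tested in cohort 1, 87.5% had the same sign there, against 60.2% of all genes.

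Treg-like cells (2350 cells) showed the interferon change of the other T cells: of 5786 genes tested, 40 rose and 8 fell. IFI44L rose by 4.54 ± 0.46 on the log2 scale (SE, n = 17, adjusted p = 1.35e-07, 198 ± 110 CPM in SjD and 16.98 ± 31.3 in control samples, SD). IFI44 rose by 2.33 ± 0.23 (adjusted p = 1.35e-07, 9 of 9 SjD samples higher) and EIF2AK2, the antiviral kinase PKR, by 1.54 ± 0.19 (adjusted p = 2.77e-06, 8 of 9). Genes that fell included FOS by 1.07, JUN, its AP-1 partner, by 0.90, TAFA1, a chemokine-like peptide, by 1.19, and LINC00910 by 1.12. IL12RB2 had a log2 value of 0.98 (adjusted p = 0.0564, 8 of 9 SjD samples higher) and CCL5, a T cell chemokine, 0.65 (adjusted p = 0.341).

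Of 17 type I interferon genes in Treg-like cells, 15 rose (17 when adjusted over the list alone, median 1.54, adjusted p = 0.0503 with an estimated correlation). Of 9 genes of the IFN-γ response, 1 rose (6 over the list alone, median 0.56, adjusted p = 0.109 with an estimated correlation). The Treg identity list was not called (camera adjusted p = 0.792). FOXP3 had a log2 value of 0.49 (adjusted p = 0.494), IL2RA -0.45 (adjusted p = 0.237), CTLA4 -0.34 (adjusted p = 0.431) and IKZF2 -0.17 (adjusted p = 0.793). The immediate early and stress list fell with 2 of 16 members (11 over the list alone, median -0.52, adjusted p = 0.179 with an estimated correlation), and PPP1R15A, a stress-induced phosphatase subunit, had a log2 value of -0.89 (adjusted p = 0.0701). The Th1 list (median 0.63, camera adjusted p = 0.0229, and adjusted p = 0.407 with an estimated correlation) was higher, with 0 of 6 members past the threshold in edgeR, 3 at an unadjusted p under 0.05 and 3 over the list alone. So was the MHC class II list (2 of 5, 4 over the list alone, median 0.61, adjusted p = 0.339 with an estimated correlation), with HLA-DRA at 0.73. In cohort 1 the list's median was -0.11, on the other side of 0, with HLA-DRA at -0.01. IGKC, the antibody light chain, rose by 1.40 in these cells and could not be tested in cohort 1. The count of genes fell to 25 without SjD 8 and was 167 and 59 under 2 other clustering seeds, and 1 gene passed in cohort 1 alone.

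CD8 T-like cells (12982 cells) rose in interferon genes and changed in others: of 10710 genes tested, 135 rose and 166 fell. OAS1, a sensor of viral double-stranded RNA, rose by 2.45 ± 0.30 on the log2 scale (SE, n = 17, adjusted p = 0.000344, 26.7 ± 11.9 CPM in SjD and 5.55 ± 4.16 in control samples, SD). TYMP, thymidine phosphorylase, rose by 1.47 ± 0.18 (adjusted p = 0.000344), and PARP9, an interferon-induced ADP-ribosyltransferase, by 1.24 ± 0.15 (adjusted p = 0.000344). These genes were higher in 9 of 9 SjD samples. CX3CR1, the fractalkine receptor of effector cells, rose by 1.91 ± 0.42 (adjusted p = 0.0249, 53.5 ± 31.8 CPM against 16.1 ± 11.02, 9 of 9 samples). Genes that fell included TOB1, which restrains T cell proliferation, by 0.91 ± 0.16 (adjusted p = 0.00636, lower in 9 of 9 SjD samples), NEXMIF by 1.72, AKAP6, a kinase anchoring protein, by 1.95, and DANCR, a non-coding RNA, by 0.59.

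Of 29 type I interferon genes in CD8 T-like cells 26 rose (27 when adjusted over the list alone, median 1.49, adjusted p = 0.0529 with an estimated correlation). Of 12 genes of the IFN-γ response, 3 rose (7 over the list alone, median 0.57, adjusted p = 0.185 with an estimated correlation). The cytotoxic list was higher as a list (median 0.95, camera adjusted p = 2.28e-05, and adjusted p = 0.413 with an estimated correlation). Of its 16 members 1, CX3CR1, passed, and 10 when adjusted over the list alone, while PRF1, which encodes perforin, had a log2 value of 1.05 (adjusted p = 0.0653). The exhaustion list (median 0.70, camera adjusted p = 0.00188, and adjusted p = 0.179 with an estimated correlation) had 0 of 8 members past the threshold in edgeR, 5 at an unadjusted p under 0.05 and 4 over the list alone. LAG3, an inhibitory receptor, had a log2 value of 1.00 (adjusted p = 0.0805) and TOX 0.70 (adjusted p = 0.0526). The naive and memory T cell list was lower as a list (median -0.64, camera adjusted p = 4.83e-05, and adjusted p = 0.396 with an estimated correlation), with 0 of 11 members past the threshold in edgeR, 3 at an unadjusted p under 0.05 and 2 over the list alone. LEF1, a transcription factor of naive T cells, had a log2 value of -0.79 (adjusted p = 0.217). The immediate early and stress list fell with 2 of 20 members (11 over the list alone, median -0.60, adjusted p = 0.396 with an estimated correlation), FOSB by 1.08 and FOS by 1.24. IFNG had a log2 value of 0.36 (adjusted p = 0.644) and TBX21 0.70 (adjusted p = 0.209). B cell markers passed with 5 of 8 members (6 over the list alone, median 1.03, adjusted p = 0.0541 with an estimated correlation), with IGKC at 1.2 and JCHAIN at 2.13. The MHC class II list passed with 3 of 7 (7 over the list alone, median 0.69, adjusted p = 0.247 with an estimated correlation). Within cohort 1 the 2 medians were 0.24 and 0.08. The makeup of the class differed in the same sense as these lists: naive-like cells were 18.2% of CD8 T-like cells in SjD and 36.6% in control samples, and cytotoxic-like cells 61.8% and 47.8%. The largest cluster was a cytotoxic-like one in SjD (24.96% of the class) and a naive-like one in control samples (35.5%). Within naive-like, memory-like and cytotoxic-like CD8 T cells taken alone, the cytotoxic list had medians of 1.19, 0.11 and 0.43, and the naive and memory list of -0.18, -0.20 and -0.38. In cohort 1 these medians were 0.02, -0.07 and 0.34 for the cytotoxic list and 0.06, 0.16 and -0.11 for the naive and memory list. The rise of the cytotoxic list in naive-like cells was thus not seen within the single pool. The count of genes ranged from 89 without SjD 8 to 405 without SjD 3. In cohort 1 alone 0 genes passed in edgeR (564 at an unadjusted p under 0.05, and 0 by DESeq2).

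NK-like cells (6887 cells) also carried the interferon change: of 9291 genes tested, 71 rose and 30 fell. IFI6, an interferon-induced mitochondrial protein, rose by 1.72 ± 0.19 on the log2 scale (SE, n = 17, adjusted p = 6.15e-05, 176 ± 61.1 CPM in SjD and 52.9 ± 11 in control samples, SD). IRF9, a transcription factor of the interferon response, rose by 1.09 ± 0.13 (adjusted p = 9.11e-05, 132 ± 15.5 CPM against 62.9 ± 22.9) and TYMP by 1.40 ± 0.17 (adjusted p = 0.000111). These genes were higher in 9 of 9 SjD samples. FEZ1, an axonal transport adaptor, fell by 1.49 ± 0.21 (adjusted p = 0.000426, 17 ± 5.93 CPM against 49.1 ± 17.9, lower in 9 of 9 SjD samples, -1.40 in cohort 1). AGAP1, a regulator of endosomal traffic, fell by 1.5, ZNF595, a zinc finger protein, by 1.16 and PGGHG, a glycosidase, by 0.86.

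Of 28 type I interferon genes in NK-like cells 25 rose (26 when adjusted over the list alone, median 1.28, adjusted p = 0.0402 with an estimated correlation). Of 11 genes of the IFN-γ response, 1 rose (3 over the list alone, median 0.11, adjusted p = 0.363 with an estimated correlation). The immediate early and stress list was lower (median -0.71, camera adjusted p = 3.62e-09, and adjusted p = 0.314 with an estimated correlation), with 0 of 20 members past the threshold in edgeR, 14 at an unadjusted p under 0.05 and 13 over the list alone. JUN had a log2 value of -1.6 (adjusted p = 0.0585) and CD69, an early activation marker, -0.99 (adjusted p = 0.0866). IFNG had a log2 value of -0.95 (adjusted p = 0.289) and TBX21 0.18 (adjusted p = 0.648). B cell markers passed with 5 of 7 members (6 over the list alone, median 1.16, adjusted p = 0.0686 with an estimated correlation), with IGKC at 1.34, and their median in cohort 1 was 0.03. The MHC class II list rose beside them (3 of 6 members, 5 over the list alone, median 0.63, adjusted p = 0.0686 with an estimated correlation), with 0.15 in cohort 1. In cohort 1 alone 4 genes passed.

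B-like cells (18081 cells) rose in many interferon genes: of 11177 genes tested, 94 rose and 34 fell. USP18, which removes ISG15 from proteins, rose by 3.8 ± 0.39 on the log2 scale (SE, n = 17, adjusted p = 6.38e-05, 15.3 ± 6.95 CPM in SjD and 0.936 ± 0.888 in control samples, SD). NRIR, a non-coding RNA of the interferon response, rose by 4.64 ± 0.49 (adjusted p = 6.38e-05). USP18 and NRIR were higher in 9 of 9 SjD samples. XAF1, a gene that promotes apoptosis, rose by 2.11 and EIF2AK2 by 1.49. LYPD6B fell by 1.87, RADX, which protects replication forks, by 0.88, LINC00910 by 1.03, PTCHD1-AS, a non-coding RNA, by 1.66 and MT-ATP8, a mitochondrial ATP synthase gene that overlaps MT-ATP6, by 0.54.

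Of 29 type I interferon genes in B-like cells 27 rose (28 when adjusted over the list alone, median 1.83, adjusted p = 0.0402 with an estimated correlation). Of 12 genes of the IFN-γ response, 2 rose (7 over the list alone, median 0.45, adjusted p = 0.11 with an estimated correlation, TAP1 by 0.91), while GBP5 had a log2 value of 0.50 (adjusted p = 0.173). TBX21, which marks atypical memory B cells, had a log2 value of 0.04 (adjusted p = 1). CTSH, cathepsin H, was the 1 of 5 tested members of the Th17 list that fell, by 0.73 (1 also over the list alone, median -0.32, adjusted p = 0.105 with an estimated correlation). It is a lysosomal protease that B cells express. The mitochondrially encoded list fell with 3 of 13 members (12 over the list alone, median -0.37, adjusted p = 0.134 with an estimated correlation). The count of genes ranged from 58 without SjD 8 to 196 without control 4, and 1 gene passed in cohort 1 alone.

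CD14 monocyte-like cells (8870 cells) showed the widest interferon change: of 10392 genes tested, 133 rose and 22 fell. SIGLEC1 (chromosome 20, 3686970 to 3707128), a sialic acid receptor induced by type I interferon on monocytes, rose by 3.13 ± 0.39 on the log2 scale (SE, n = 17, adjusted p = 0.000285, 74.7 ± 32.4 CPM in SjD and 8.55 ± 6.34 in control samples, SD, 2.94 in cohort 1). IFI27 rose by 6.86 ± 1.06 (adjusted p = 0.00117, 330 ± 422 CPM against 3.13 ± 5.32). HERC5, the ligase that attaches ISG15, rose by 2.02, OAS3 by 1.97, IRF7, the transcription factor that amplifies interferon production, by 1.55, EIF2AK2 by 1.37, TRIM22, an antiviral ubiquitin ligase, by 1.11 and RNF213, a large ubiquitin ligase, by 0.97. KIAA1958 rose by 1.41. Each of these was higher in 9 of 9 SjD samples. GBP1 rose by 1.68 (adjusted p = 0.0161, 9 of 9) and SERPING1, the inhibitor of complement C1, by 2.27 (adjusted p = 0.00944, 9 of 9).

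Of 30 type I interferon genes in CD14 monocyte-like cells 29 rose (30 when adjusted over the list alone, median 2.01, adjusted p = 0.0402 with an estimated correlation). Of 15 genes of the IFN-γ response, 7 rose (8 over the list alone, median 0.80, adjusted p = 0.247 with an estimated correlation), including APOL6, an apolipoprotein L, by 0.80. The TNF and NF-κB list was lower (median -0.49, camera adjusted p = 0.00298, and adjusted p = 0.6 with an estimated correlation), with 0 of 19 members past the threshold in edgeR, also over the list alone, and 4 at an unadjusted p under 0.05. It was also called lower in CD4 T-like, CD8 T-like, NK-like and B-like cells, with medians of -0.32, -0.25, -0.46 and -0.25 (adjusted p = 0.412 to 0.6 with an estimated correlation over the 5 classes). CXCL2 and CXCL8, chemokines that recruit neutrophils, had log2 values of -1.82 (adjusted p = 0.167) and -1.10 (adjusted p = 0.375), and NFKB1, an NF-κB subunit, -0.99 (adjusted p = 0.331). The inflammasome and complement list was higher (median 0.23, camera adjusted p = 0.0348, and adjusted p = 0.429 with an estimated correlation) with 1 of 14 members past the threshold, SERPING1, also over the list alone. Mitochondrially encoded genes fell (3 of 13, and 13 over the list alone, median -0.39, adjusted p = 0.134 with an estimated correlation), MT-ATP8 by 0.59, MT-ATP6 by 0.44 and MT-CO1, a subunit of cytochrome c oxidase, by 0.47. PIK3R5, a PI3K subunit, fell by 0.89, ITPKB, an inositol trisphosphate kinase, by 0.70, MBNL2, a splicing regulator, by 0.58, RPH3A, a vesicle protein, by 1.06, ITGAE, the integrin chain CD103, by 0.70, FAM174B by 0.76 and TBC1D12 by 0.79. The antisense RNAs KMT2E-AS1 and MBNL1-AS1 fell by 0.53 and 0.89, with reads that can be hard to assign where genes overlap. B cell markers were higher here too (6 of 7 members, 6 over the list alone, median 1.41, adjusted p = 0.0664 with an estimated correlation), with IGKC at 1.51 and CD79A, a chain of the B cell receptor, at 1.6. Their median in cohort 1 was 0.03. In cohort 1 alone 0 genes passed in edgeR (704 at an unadjusted p under 0.05, and 3 by DESeq2). There the type I interferon list had a median of 1.72.

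CD16 monocyte-like cells (2074 cells) shared the interferon change: of 7697 genes tested, 74 rose and 11 fell. IFIT3, an interferon-induced inhibitor of viral translation, rose by 2.39 ± 0.26 on the log2 scale (SE, n = 17, adjusted p = 2.16e-05, 179 ± 79.5 CPM in SjD and 38.6 ± 10.4 in control samples, SD). XAF1 rose by 1.79 ± 0.19 (adjusted p = 2.16e-05), and both were higher in 9 of 9 SjD samples. CMPK2, a mitochondrial nucleotide kinase, rose by 2.14, IFI6 by 2.39 and IFI44 by 2.49. LYPD2 fell by 1.92 ± 0.35 (adjusted p = 0.00361, 124 ± 107 CPM against 475 ± 163, lower in 8 of 9 SjD samples, -2.27 in cohort 1), KRT10, a keratin, by 0.85 and EIF1, a translation initiation factor, by 0.51.

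Of 28 type I interferon genes in CD16 monocyte-like cells 25 rose (28 when adjusted over the list alone, median 1.61, adjusted p = 0.0402 with an estimated correlation). Of 11 genes of the IFN-γ response, 3 rose (7 over the list alone, median 0.73, adjusted p = 0.247 with an estimated correlation). The monocyte marker list was higher (median 0.63, camera adjusted p = 5.54e-05, and adjusted p = 0.347 with an estimated correlation), with 0 of 10 members past the threshold in edgeR, 5 at an unadjusted p under 0.05 and 5 over the list alone. CD14, a lipopolysaccharide co-receptor, had a log2 value of 1.61 (adjusted p = 0.0966, higher in 9 of 9 SjD samples) and S100A8, a calcium-binding alarmin, 0.86 (adjusted p = 0.153). MT-ATP6 fell by 0.55 and MT-ND4L, a gene that overlaps MT-ND4, by 0.50, within a mitochondrially encoded list in which 3 of 13 members fell (13 over the list alone, median -0.50, adjusted p = 0.134 with an estimated correlation). The count of genes was 148 without SjD 3 and 51 without control 6. In cohort 1 alone 0 genes passed in edgeR (246 at an unadjusted p under 0.05, and 1 by DESeq2).

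Over all 26 lists that could be tested, 71 of 165 tests were called by camera with its preset correlation, 42 higher and 29 lower in SjD, and 65 of the 71 had the same direction in cohort 1. Cohort 1 is part of the samples behind these calls, so this agreement is in part built in. With an estimated correlation 4 calls held, all for type I interferon genes, in the NK-like, B-like, CD14 monocyte-like and CD16 monocyte-like classes. With fry, 34 tests passed, 32 of them also called by camera. Other calls by camera included lower immediate early and stress genes (median -0.39) and higher B cell markers (0.18) and monocyte markers (0.27) in B-like cells, higher cytotoxic genes in CD14 monocyte-like cells (0.18) and higher atypical B cell genes in CD8 T-like cells (0.43), with adjusted p = 0.134 to 0.587 with an estimated correlation. The type I interferon list kept a median of 0.62 to 1.72 in cohort 1 over the 7 classes. Ribosomal protein and mitochondrially encoded genes were lower in all 7 classes, with medians of -0.49 to -0.16 and -0.50 to -0.29. The 100 splits drawn within cohorts, the real one included, gave at most 101 genes in any class other than by the real split.

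**Figure D3:**
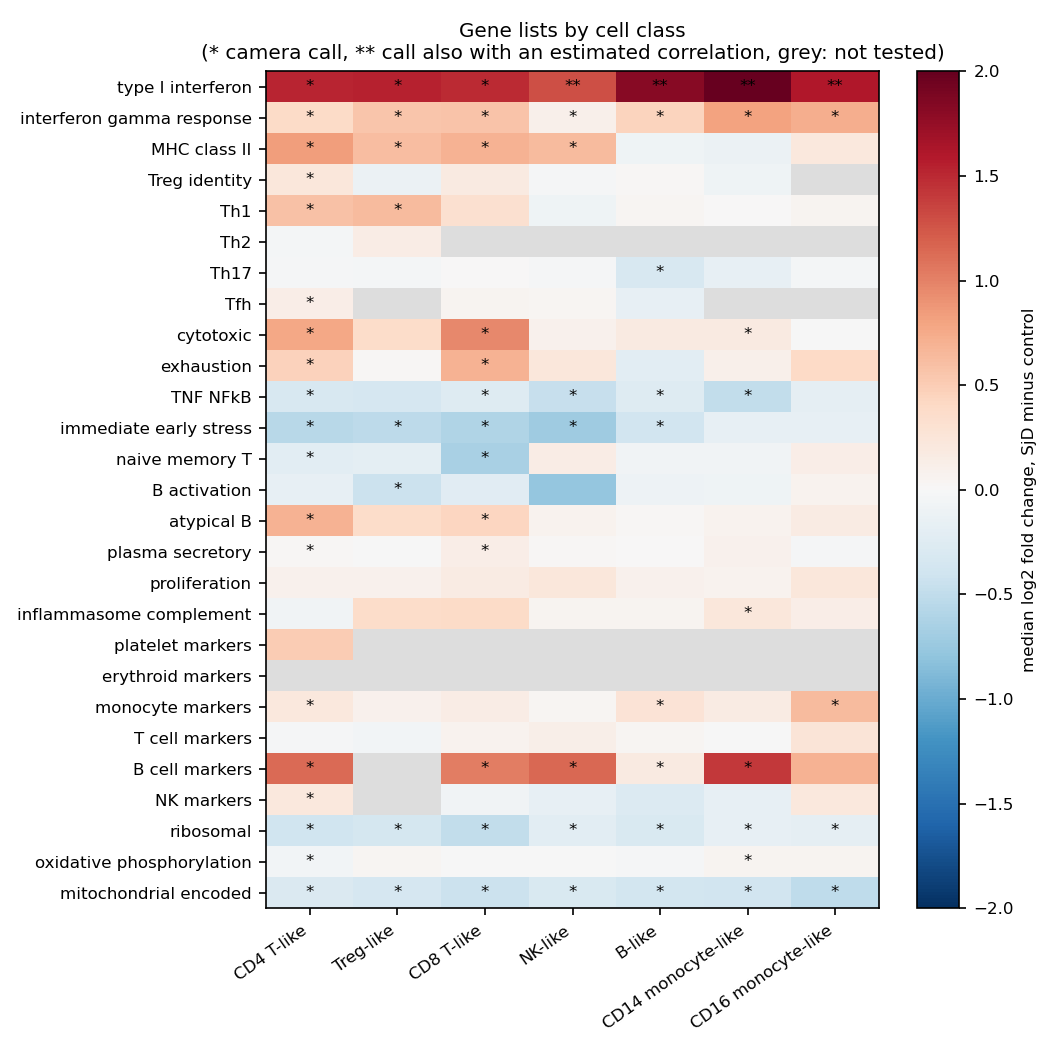
Median log2 fold change (SjD over control) of each fixed gene list in the 7 cell classes, with 1 asterisk for a camera call and 2 for a call that held with an estimated correlation. Type I interferon genes have medians of 1.28 to 2.01, the highest of the lists shown in each class.

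**Figure D4:**
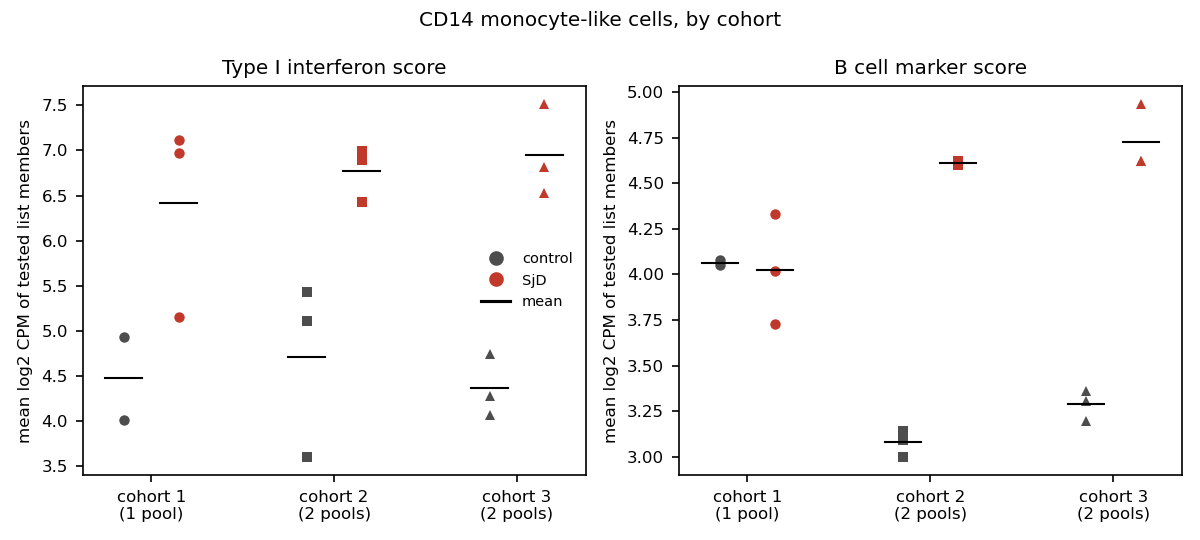
Mean log2 CPM of the type I interferon list (left) and of the B cell markers (right) in CD14 monocyte-like cells, per sample and cohort. Lines are means. In cohort 1, whose samples shared a capture pool, the interferon list had a median log2 change of 1.72 and the B cell markers one of 0.03.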

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

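Of the tests in this part, those by cohort, those in naive CD4 T-like cells and in other parts of a class, with a doublet score limit of 0.1 and with clusters led by B or NK markers left out were chosen after the data were seen. The readings of capture pools for the interferon genes and the B-like share were chosen after their own results were seen. So was the reading of the mix of cells within B-like cells for the interferon genes. The decision to read the pool tests as open, because an exact test in cohort 1 cannot go below p = 0.1, was also made then. The comparison with other splits and the B-like share with doublets kept were planned.

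Type I interferon genes were higher in SjD in 7 of 7 classes. The mix of cells within a class is argued against as the whole cause in 4 classes, since the list had a median log2 change of 1.47 in naive CD4 T-like cells alone, with 28 of 28 members above 0, of 1.40 in naive-like and 1.304 in cytotoxic-like CD8 T cells, of 1.31 in CD56dim NK-like and of 1.82 in naive B-like cells. In the Treg-like and monocyte-like classes no part was tested alone. A difference between capture pools cannot be told apart from disease in cohorts 2 and 3, and in cohort 1, a single pool, the list's median was 1.72 in CD14 monocyte-like cells, with exact permutation p = 0.2 for the mean. The difference in cohort 1 came mainly from SjD 1 and SjD 2. SjD 3 lay between the controls of that cohort in CD4 T-like, Treg-like, NK-like and CD16 monocyte-like cells. Of the genes called in cohorts 2 and 3, 83.9% (Treg-like cells) or more per class had the same sign in cohort 1, against 55.7% to 60.5% of all genes. Exposure to type I interferon in the disease may account for the pattern, which is a hypothesis found and read on the same data, and pool effects in cohorts 2 and 3 stay open.

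B cell genes were higher in SjD in cells that are not B cells, with medians of 1.13 in CD4 T-like, 1.03 in CD8 T-like, 1.16 in NK-like and 1.41 in CD14 monocyte-like cells. In CD16 monocyte-like cells the median was 0.70, with 5 of 7 members above 0, and the list was not called (camera adjusted p = 0.1001). RNA carried over between cells of the same capture pool is a candidate source. In CD14 monocyte-like cells the median was 0.026 in cohort 1 (quartiles -0.27 to 0.31), where both groups shared a pool, and 1.83 in cohorts 2 and 3, where they did not. For the gap between these cohorts, a permutation of the group labels within cohorts gave p = 0.00175. The same permutation gave p = 0.0127 in NK-like, 0.00975 in CD8 T-like, 0.0145 in CD4 T-like and 0.119 in CD16 monocyte-like cells. The CD16 monocyte-like medians were -0.28 in cohort 1 and 0.79 in cohorts 2 and 3. This permutation assumes no group effect in any cohort, so a low p does not by itself show that the cohorts differ. B cells in the same droplet are argued against as the whole cause in CD14 monocyte-like cells, since 111% of the median was kept there when cells with a doublet score above 0.1 were also left out. The cells kept held 94.5% of the UMIs of the class, so this limit removed little. It tests doublets only as far as the score finds them. In CD4 T-like cells, which held a cluster of 324 cells led by B cell genes, B cells or doublets in that cluster are argued against as the whole cause, since 91.4% of the median was kept with the clusters led by B or NK markers left out. They stay open as a part of it, since the median in cohort 1 went from 0.22 to -0.14. A true expression of B cell genes in these cells was not tested and stays open.

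The B-like share was higher in SjD, by 1.03 on the log2 scale. Doublet removal is argued against as the cause, since the difference was 1.01 with doublets kept. A difference between pools cannot be told apart from disease: the difference was 0.31 in cohort 1, and a permutation of the group labels within cohorts gave p = 0.137 for a difference between cohort 1 and the others. That permutation assumes no group effect in any cohort, so it does not test the gap between cohorts alone. A change of B cell numbers in the disease may be behind it and stays open.

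The number of genes called was compared with other splits of the samples within cohorts, 100 in each class with the real split included. Chance is argued against in 7 of 7 classes, as only 1 split, the real split, gave as many. It is not excluded, since 100 of 4000 possible arrangements were drawn and all classes come from the same donors. The splits cannot tell capture pool from disease in cohorts where each group had a pool of its own. The real and the highest other counts were 287 and 101 in CD4 T-like, 48 and 41 in Treg-like, 301 and 38 in CD8 T-like, 101 and 44 in NK-like, 128 and 98 in B-like, 155 and 25 in CD14 monocyte-like and 85 and 53 in CD16 monocyte-like cells.

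Of 448 groups of samples looked at, 38 held a sample far from the others of its group, where chance gives about 1 in 20, or 22. The number given in this paragraph and the next is its gap to the nearest sample over the group's range, compared with the 95% critical value of Dixon's test. Of the groups, 23 were of SjD and 15 of control samples. In 21 of the SjD groups the sample was the lowest, and in 18 of these it was 1 and the same sample. Among shares, 1 of 9 SjD samples was highest in MAIT-like cells (0.812, 1.64% against 0.324%) and in Th1-like cells of CD4 T-like cells (0.517, 28.0% against 15.3%). Of the control samples, 1 of 8 was highest in naive-like cells of CD8 T-like cells (0.540, 76.0% against 43.5%) and 1 of 8 in NK-like cells with an IFNG UMI (0.678, 28.1% against 9.72%).

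Among interferon genes, 1 of 9 SjD samples was lowest for MX1 in CD4 T-like cells (0.514), IFI44L in Treg-like cells (0.627) and GBP1 in NK-like cells (0.514). The lowest of 9 SjD samples stood apart as well for KIAA1958 (0.603), HERC5 (0.548), EIF2AK2 (0.583), OAS3 (0.610), SIGLEC1 (0.628), PARP9 (0.505), IFI44L (0.580) and MX1 (0.679) in CD14 monocyte-like cells. The same held for IFIT3 (0.549), IFI6 (0.5255), IFI44 (0.657), MX1 (0.756) and IFI44L (0.581) in CD16 monocyte-like cells, and the type I interferon score in CD14 (0.537) and CD16 monocyte-like cells (0.540). For both scores the lowest sample was SjD 3, of cohort 1. Of the control samples 1 of 8 was lowest for EIF2AK2 in B-like (0.556) and RNF213 in CD14 monocyte-like cells (0.660). Also, 1 of 8 was highest for IFI44L (0.572) and MX1 (0.530) in Treg-like, IFI27 in NK-like (0.699) and CMPK2 in CD16 monocyte-like cells (0.699). Among other genes, 1 of 9 SjD samples was lowest for IGHM in CD4 T-like cells (0.538), and LINC00910 (0.5264) and IKZF2 (0.569) in Treg-like cells. A control sample was lowest for NIBAN3 (0.542) and IL2RA (0.562) in CD4 T-like cells, IKZF2 in CD8 T-like cells (0.576), PTCHD1-AS (0.689) and TBX21 (0.596) in B-like cells and RPH3A in CD14 monocyte-like cells (0.585), and highest for MT-ATP6 in CD16 monocyte-like cells (0.599). For PTCHD1-AS and TBX21 in B-like cells the lowest value was the same, -0.951 log2 CPM. That value probably stands for no UMI found.

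The interferon change differed between classes: over the 17 members tested in all classes it was larger than in CD4 T-like cells by 0.63 in CD14 monocyte-like and by 0.32 in B-like cells (permutation test of the difference, adjusted p = 0.00375 each), and by 0.31 in CD16 monocyte-like cells (adjusted p = 0.0415). The differences in Treg-like (0.12, adjusted p = 0.292), CD8 T-like (0.07, adjusted p = 0.515) and NK-like cells (0.00, adjusted p = 0.961) did not pass.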

How the results depend on the processing

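The settings that use single cohorts, or naive or memory cells alone, the replicate block for list tests, the clusters led by B or NK markers left out and the 2 other clustering seeds were chosen after the data were seen. The other alternatives were planned, and for each result that changed, the cause was not tested except where fewer samples, cells or tested genes are named. Depth limits the classes with few cells: CD16 monocyte-like and Treg-like samples went down to 28 and 30 cells, and median depth per cell was lowest in cohort 1. Cohort 1 holds 5 samples, so few genes could pass there. Of 152 named genes that passed, 127 passed with each sample left out in turn. All 202 named genes kept direction and call with RLE size factors and with at least 30 cells per sample, and 195 and 200 did with clustering seeds 2 and 3. Without the cohort term 64 of the 152 were lost, in the replicate block 52, in cohorts 2 and 3 alone 25 of 151 and with doublets kept 8. Of 183 named genes tested in cohort 1 alone, 173 kept direction, and none of the 139 among the 183 that passed over all samples passed there. Since cohort 1 is part of the samples of the main fit, the kept direction is in part built in.

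The Treg-like share of CD4 T-like cells (0.42, exact permutation p = 0.166) kept its direction and stayed uncalled in 10 of 10 settings, with 0.40 and 0.25 under clustering seeds 2 and 3 and 0.13 at the lowest, but it was -0.12 in cohort 3. Without 1 sample it was 0.29 (control 2) to 0.58 (SjD 7, where exact permutation p = 0.0385). The Th1-like share of CD4 T-like cells (0.58, exact permutation p = 0.097) had an unadjusted p under 0.05 with doublets kept (0.99, exact permutation p = 0.0107), by edgeR (0.66, p = 0.0245, but adjusted p = 0.105 over the shares) and without SjD 4 (0.76, exact permutation p = 0.023). Among the fits with 1 sample left out it was lowest without SjD 9 (0.43). Under clustering seeds 2 and 3 it was 0.30 and 0.42. The share of CD4 T-like cells with a FOXP3 UMI (0.63, exact permutation p = 0.0385) was not called at 1000 UMIs (0.86), without thinning (0.51) or in cohort 1 alone (0.78, fewer samples). Nor was it without control 1 (0.52), control 3 (0.58), control 6 (0.52), SjD 2 (0.53), SjD 5 (0.56) or SjD 8 (0.48), and the highest was 0.73 (SjD 7). Of the cell class shares, 2 passed with raw percentages, by edgeR, with clustering seed 3 and without control 2, the B-like and naive B-like shares in each case, and 3 with clustering seed 2 or without SjD 3. Without SjD 5 it was 4, without SjD 7 6, and the lowest count without 1 sample was 0. The IFNG share of NK-like cells was -0.82 without control 8 (exact permutation p = 0.01) and -0.30 at the other end, and that of CD4 T-like cells was -0.14 in cohort 1.

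The count of genes changed in CD4 T-like cells (287) was 515 by DESeq2 (286 shared), 551 without a count filter, 52 without the cohort term, 71 in the replicate block, 0 in cohort 1 by edgeR (552 at an unadjusted p under 0.05, 0 by DESeq2) and 115 in naive cells, with fewer cells. It was 340 and 308 with clustering seeds 2 and 3 (266 and 260 shared), and 251 with the clusters led by B or NK markers left out (245 shared). Without 1 sample it was 165 (SjD 2), 154 (SjD 6), 174 (control 7), 172 (control 8), 157 (SjD 9), with a range of 127 (SjD 8) to 436 (SjD 7). For genes changed in Treg-like cells (48) it was 75 by DESeq2 (44 shared), 127 without a count filter, 22 without the cohort term, 24 in the replicate block, 167 with clustering seed 2 (45 shared), 59 with seed 3 and 1 in cohort 1, and without 1 sample 25 (SjD 8) to 70 (SjD 3). For genes changed in CD8 T-like cells (301) it was 508 by DESeq2 (297 shared), 1204 without a count filter, 38 without the cohort term, 77 in the replicate block, 0 in cohort 1 by edgeR (564 at an unadjusted p under 0.05, 0 by DESeq2) and 121 in cohorts 2 and 3. Without 1 sample it was 187 (control 1), 154 (SjD 1), 123 (SjD 2), 149 (control 3), 175 (control 5), 158 (SjD 6), 135 (control 7), 152 (control 8), 186 (SjD 7), 91 (SjD 9), with a range of 89 (SjD 8) to 405 (SjD 3). For genes changed in NK-like cells (101) it was 174 by DESeq2 (99 shared), 422 without a count filter, 41 without the cohort term, 51 in the replicate block and 4 in cohort 1 (0 shared), and without 1 sample 70 (SjD 4) to 122 (control 5). For genes changed in B-like cells (128) it was 246 by DESeq2 (124 shared), 557 without a count filter, 36 without the cohort term, 49 in the replicate block, 1 in cohort 1, 73 in cohorts 2 and 3 and 210 in naive cells. Without 1 sample it was 80 (SjD 2), 66 (SjD 4), 78 (SjD 5), 75 (control 6), 78 (control 7), with a range of 58 (SjD 8) to 196 (control 4). For genes changed in CD14 monocyte-like cells (155) it was 265 by DESeq2 (155 shared), 615 without a count filter, 97 in the replicate block and 0 in cohort 1 by edgeR (704 at an unadjusted p under 0.05, 3 by DESeq2), and without 1 sample 113 (SjD 9) to 227 (control 4). For genes changed in CD16 monocyte-like cells (85) it was 144 by DESeq2 (77 shared), 261 without a count filter, 42 without the cohort term, 48 in the replicate block and 0 in cohort 1 by edgeR (246 at an unadjusted p under 0.05, 1 by DESeq2). Without 1 sample it was 52 (SjD 9), with a range of 51 (control 6) to 148 (SjD 3). Of the 71 gene list tests called, 4 held with an estimated correlation, fry called 34 (32 shared), and cohort 1 gave 39 (35 shared). Without 1 sample 59 to 73 were called.

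In cohort 1 these genes changed sign: in CD4 T-like cells JCHAIN -0.26, CTLA4 0.11 and IFNG -0.35, in Treg-like cells IKZF2 0.14 and HLA-DRA -0.00903, in CD8 T-like cells IFNG -0.16, IGKC -0.041 and HLA-DRA -0.026, and in NK-like cells IKZF2 -0.00935 and HLA-DRA -0.16. Of these, JCHAIN, IGKC and HLA-DRA were called over all samples. IFNG in CD4 T-like cells was -0.084 in memory cells, and IL2RA was 0.20 in naive CD4 T-like cells. CTLA4 in CD8 T-like cells was -0.22 with clustering seed 2. TBX21 in B-like cells was -0.072 in the replicate block and -0.049 in cohorts 2 and 3. Without 1 sample IFNG in CD4 T-like cells was -0.17 (SjD 9) to 0.54 (control 3), also below 0 without control 1 (-0.000382), control 5 (-0.016) or control 8 (-0.078). TBX21 in B-like cells was -0.26 (SjD 9) to 0.20 (SjD 8), also below 0 without control 1 (-0.017), control 7 (-0.12) or SjD 6 (-0.022).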

Other observations

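The values of this part come from lists and markers fixed beforehand and from classes whose naming thresholds were set after the data were seen, and no test here was chosen after its result was seen except the IFNG share of Th1-like cells and the FOXP3 share of Treg-like cells.

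Other cell classes showed these shares. Plasmablast-like cells were 0.392% of SjD and 0.118% of control cells (exact permutation p = 0.0742, adjusted p = 0.186, log2 difference 1.30, 6 of 9 SjD samples above the control mean of their cohort). SjD 9 held 1.89% and the other 8 SjD samples 0.0502% to 0.389%, so much of the difference in means comes from SjD 9. Proliferating cells were 0.271% and 0.119% (exact permutation p = 0.0568, adjusted p = 0.17, log2 difference 0.98, 8 of 9 above, 1.55 in cohort 1). Atypical B-like cells were 1.08% and 0.521% (exact permutation p = 0.0665, adjusted p = 0.181, log2 difference 1.00, 1.02 in cohort 1). Gamma delta T-like cells were 2.05% and 1.09% (exact permutation p = 0.199), with 9.44% in SjD 6 and 0.645% to 1.59% in the other 8 SjD samples, so most of the difference in means comes from SjD 6. The log2 differences were -0.46 for NK-like, 0.17 for CD8 T-like, 0.25 for CD14 monocyte-like, 0.34 for CD16 monocyte-like and -0.39 for conventional dendritic-like cells, with exact permutation p from 0.19 to 0.611. Of Th1-like cells, 2.56% in SjD and 2.50% in control samples held an IFNG UMI (exact permutation p = 0.657). The Th1-like class held 2 clusters, and each held a large part of the cells of both groups. In SjD, 57.04% lay in the one led by LINC00892, GZMK and LGALS3 (Th1 marker score 0.81). In control samples, 51.6% lay in the one led by IFNG-AS1, GZMK and TPRG1 (score 2.05). These percentages are of cells pooled over samples and were not tested. Of Treg-like cells 5.41% and 4.11% held a FOXP3 UMI (exact permutation p = 0.137).

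Of the lists not described in the report, those of general T cell markers, Th2 cells, platelets and proliferation were called in no class by camera. Their lowest adjusted p over the classes was 0.477, 0.344, 0.0732 and 0.0868. Oxidative phosphorylation genes were lower in CD4 T-like cells (3 of 76 members, 4 over the list alone, median -0.06, camera adjusted p = 0.0316, and adjusted p = 0.619 with an estimated correlation) and higher in CD14 monocyte-like cells (0 of 75 members in edgeR, 7 at an unadjusted p under 0.05, 0 over the list alone, median 0.05, camera adjusted p = 0.0143, and adjusted p = 0.587 with an estimated correlation). Genes of antibody secretion were higher as a list in CD4 T-like cells (3 of 9 members, 3 over the list alone, median 0.03, camera adjusted p = 0.0127, and adjusted p = 0.363 with an estimated correlation) and CD8 T-like cells (2 of 8 members, 2 over the list alone, median 0.14, camera adjusted p = 0.0416, and adjusted p = 0.396 with an estimated correlation). B cell activation genes were lower as a list in Treg-like cells (0 of 4 members in edgeR, 2 at an unadjusted p under 0.05, 2 over the list alone, median -0.44, camera adjusted p = 0.039, and adjusted p = 0.179 with an estimated correlation). NK cell markers (0 of 10 members in edgeR, 3 at an unadjusted p under 0.05, 1 over the list alone, median 0.21, camera adjusted p = 0.0348, and adjusted p = 0.587 with an estimated correlation) and monocyte markers (1 of 11 members, 1 over the list alone, median 0.22, camera adjusted p = 0.0167, and adjusted p = 0.396 with an estimated correlation) were higher as lists in CD4 T-like cells.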
